A study of Mus musculus with 12 samples.

How the data were processed

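RNA sequencing counts were deposited for 12 libraries of MC3T3-E1 cells: 3 from each of isolated and co-cultured cells on control titanium and on titanium with nanotopography. RANKL at 50 ng/mL drove the RAW 264.7 cells, and osteoblasts were kept in 7 mM β-glycerophosphate and 5 µg/mL ascorbic acid, both for 5 days apart and 2 days together; total RNA was taken with TRIzol on day 7 and libraries were built with SMARTer chemistry. The deposited values are raw read counts per gene, 1 library per file, as the authors' counting step left them. Per the submitters' processing notes, cutadapt, FastQC 0.63, STAR 2.4, HTSeq and DESeq2 were used with mm10; the notes give no order or role for each tool, no annotation release and no strand setting.

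The deposited gene lists, in order of Ensembl identifier, end at different genes, and 11 of the 12 end within a line. The 52654 genes complete in each were used and the 1621 further genes of the longest were left out; the genes used held at least 99.924% of each library's counts. All 52654 matched GENCODE M21 without the version suffix, and 52092 with it. M21 has 2503 genes (98 protein-coding) past the last gene used and 379 (128 protein-coding) before it with no entry, so nothing is known of these.

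Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes passing edgeR's low-count filter were tested: 13340, of which 11049 are protein-coding. Libraries were scaled by TMM, and edgeR quasi-likelihood tests on a model with 4 group means gave 7 contrasts: osteoclasts on each surface, the surface in each culture, their interaction and both averaged effects. P-values were adjusted by Benjamini-Hochberg within each contrast over all tested genes, and genes with an adjusted p below 0.05 are called. The common dispersion was 0.0151, a biological coefficient of variation of 12.3%. CPM values used TMM-scaled totals and the log scale a prior count of 2. The summed CPM of marker genes and the limits for Tnfsf11 used plain totals instead. Total counts over the genes used ran from 5866842 to 9207831. A gene at 0 counts is given with a floor of 3 counts over its group, and with 1 to 3 counts as a ratio with a 95% counting interval; intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

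The design, the gene lists and the genes to be named were fixed before the data were examined. The named genes are the 10 highest and 10 lowest log2 fold changes per contrast among called protein-coding genes with a mean CPM of at least 1 and, between groups, no overlap of the 3 and 3 libraries (10% of genes would show this by chance); a panel of 16 osteoblast and histone-methylation genes; and up to 4 members with the smallest p of each list described. Of 33 lists, 31 had at least 5 tested genes and were tested with camera (correlation of 0.01), adjusted within each contrast, with camera at an estimated correlation and fry as alternatives. Attenuation was tested with fry on the interaction of the genes called in the averaged osteoclast effect, signed by that effect, and called at 0.05; this is 1 test, so its p has no family to adjust over and the text gives the call. Alternatives were RLE and upper-quartile scaling, other low-count filters, DESeq2 1.42.0, limma-voom, protein-coding genes only, no mitochondrial genes, only the groups compared, a fold of at least 2, a replicate block and leaving out each library. After the data were seen, 4 alternatives were added: removal of each library's trend with GC content and transcript length (loess, span 0.3), that removal with the replicate block, leaving out the 3 libraries farthest along the GC axis, and attenuation in genes of 47 to 51% GC.

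The methods were tested on simulated data. Of genes changed by 1.5, 2 and 4-fold, 32.8%, 77.6% and 98.5% were recovered for osteoclasts on control titanium with 4 unchanged genes called, and 4.48%, 50.0% and 87.9% for the interaction with 6. For the surface with osteoclasts they were 40.9%, 79.7% and 92.4% with 11. With a simulated GC trend in that comparison, 6907 unchanged genes were called without the correction and 8 with it. The simulated trend was linear in GC content, equal in the 3 libraries of the group and free of true changes linked to GC. It cannot show whether the correction also removes true changes. Among 50 simulated lists, the shifted list was called and 0 of the others. The simulation did not examine correlation between genes of a list, so it gives no rate of false calls for the real lists. With an estimated correlation, 61 of the 67 real list calls were lost. In simulated attenuation, 1.25-fold larger and 0.8-fold smaller effects on nanotopography gave medians of 0.31 and -0.31, and an equal effect -0.02. Fry called that equal effect too, and 1 of 20 further draws with an equal effect.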

Results

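The libraries came from MC3T3-E1 subclone 14 cells, a mouse calvaria line of preosteoblasts, grown on titanium discs with a control surface or with nanotopography. The cells were kept alone or shared medium with osteoclasts derived from RAW 264.7 macrophages in inserts with 0.4 µm pores for the last 2 of 7 days. RANKL and inserts are recorded for co-cultures only, and no group had either without osteoclasts. What is called an osteoclast effect below is co-culture against isolated cells. Effects of osteoclasts, RANKL, the insert and added cells in shared medium cannot be told apart. Each of the 4 groups had 3 libraries, which the series labels call biological triplicates. Total counts of the 3 libraries, in order of replicate, were 7717365, 8386870 and 5866842 for isolated cells on control titanium, 6144063, 6767624 and 6014139 for isolated cells on nanotopography, 9207831, 7139534 and 6773131 for co-culture on control titanium and 7443016, 7565815 and 6392210 for co-culture on nanotopography. Values in CPM (counts scaled by library total) are means ± SD with n = 3 libraries per group, and log2 fold changes carry an approximate standard error. It is the absolute log2 fold change divided by the square root of edgeR's F statistic. Gene identifiers and coordinates are those of mm10 (GRCm38) in GENCODE M21. The strand setting of the counting is not stated, so reads from overlapping or antisense transcripts cannot be set apart.

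Library composition differed between the groups. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 took 11.6 ± 3.75% of counts (mean ± SD, n = 3) in co-culture on nanotopography, 6.49 ± 0.304% in co-culture on control titanium, 8.17 ± 1.55% in isolated cells on control titanium and 5.14 ± 1.05% in isolated cells on nanotopography. The predicted genes Gm26917 and Gm42418, where ribosomal RNA reads often align, took 0.635 ± 0.248%, 1.84 ± 0.289%, 3.81 ± 1.44% and 6.27 ± 2.38% in the same order. The list of replication-dependent histones, described below, moved the same way as this share between groups. The list was formed from the start of gene symbols, H1f among them. Its name may therefore not hold for each member, such as the linker histone gene H1fx. Its log2 medians with osteoclasts were -0.92 on control titanium and -3.46 on nanotopography. For the surface they were 1.17 without and -1.01 with osteoclasts. Whether library composition sets these values was not tested. The first principal component held 55.4% of the variance, and its loadings followed GC content across genes (Spearman rho 0.74; genes are not independent replicates). Genes under 40% GC had a median log2 fold change of 1.01 with osteoclasts on nanotopography, and genes over 60% GC one of -1.34. On control titanium the same medians were -0.25 and -0.19. For this reason log2 fold changes and list medians below that involve nanotopography are also given with each library's trend with GC content and transcript length removed, a correction chosen after the trend was seen and called GC-adjusted here.

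**Figure D1:**
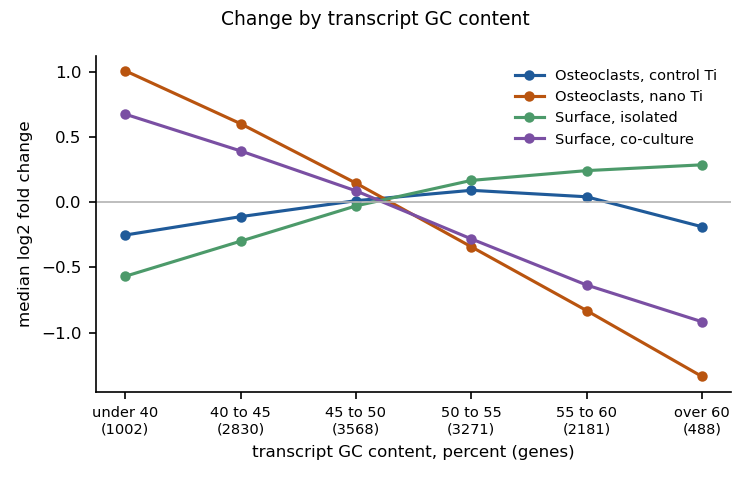
Median log2 fold change (vertical axis) of tested genes in 6 bins of transcript GC percent (horizontal axis) for each comparison. With osteoclasts on nanotopography the medians fall from 1.01 to -1.34 across the bins.

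With osteoclasts on control titanium, Hmox1, Mt2 and Slc2a1 were higher in the osteoblast libraries and Smpd3 was lower. The comparison asks how osteoblasts that share medium with osteoclasts differ from isolated ones on a plain surface. Hmox1, which encodes heme oxygenase, went from 35.6 ± 9.74 to 341 ± 13.0 CPM (log2 fold change 3.27 ± 0.15, edgeR adjusted p = 4.77e-10). The metallothionein gene Mt2 went from 6.12 ± 2.71 to 58.5 ± 12.1 CPM (log2 fold change 3.30 ± 0.22, adjusted p = 2.34e-08). The glucose transporter gene Slc2a1 rose by 1.57 ± 0.14 (adjusted p = 8.11e-07). Smpd3, a sphingomyelinase gene needed for bone mineralisation, went from 1352 ± 68.0 to 482 ± 38.8 CPM (log2 fold change -1.49 ± 0.10, adjusted p = 3.34e-08). In all, 2637 of 13340 tested genes (1468 higher and 1169 lower) passed an adjusted p of 0.05, 243 higher and 310 lower of them by at least 2-fold. The GC-adjusted count was 3602 (2032 higher and 1570 lower), and 2523 genes were called in both with the same direction. The count was 1628 without coculture control replicate 2, 1494 without isolated control replicate 1, 1432 without isolated control replicate 2. Of the 49 tested genes named for this comparison, 45 to 49 stayed on their side of the threshold when 1 library was left out, the fewest without coculture control replicate 2 or isolated control replicate 1. Calls were lost for Dmp1 (-0.83, adjusted p = 0.0687 without coculture control replicate 2), Ibsp (-0.41, adjusted p = 0.0812 without isolated control replicate 1), Runx2 (-0.28, adjusted p = 0.186 without coculture control replicate 2) and Setd7 (-0.27, adjusted p = 0.148 without coculture control replicate 2). Each log2 fold change and p is given without the library that moved the p most.

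Among the genes with the highest fold changes were Nos2 at 4.14 ± 0.42, the muscle actin gene Acta1 at 3.93 ± 0.51 and Gpnmb at 3.69 ± 0.43, with adjusted p = 3.27e-06, 3.93e-05 and 1.41e-05. These genes were near absent without osteoclasts, with 0.346 ± 0.288 CPM for Nos2 and 0.544 ± 0.246 for Gpnmb. Whether their transcripts came from the osteoblasts or from cells of the insert was not tested. The cyclooxygenase gene Ptgs2 rose by 2.27 ± 0.12, the collagenase gene Mmp13 by 1.90 ± 0.16 and the protease inhibitor gene Timp3 by 2.41 ± 0.13. The integrated stress response genes Ddit3 and Atf3 rose by 2.10 ± 0.12 and 2.57 ± 0.22. Among the lowest fold changes were the linker histone gene H1fx at -4.21 ± 0.25, the glycosyltransferase gene Galnt2 at -3.90 ± 0.42 and Scand1 at -3.34 ± 0.19. The replication-dependent histone genes Hist1h3b and Hist1h2ak had -4.11 ± 0.43 and -3.82 ± 0.37, but histone genes have near-identical copies and the values of single copies are uncertain. Rps2, a ribosomal protein gene with processed pseudogenes, had -2.71 ± 0.19, with the same uncertainty. That uncertainty also applies to the single histone and ribosomal protein genes named below.

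By lists of genes fixed before the data were examined, hypoxia and glycolysis had 21 higher, 0 lower and 6 not called of 27 tested genes (23 higher and 1 lower adjusted over the list alone). The log2 median was 0.70 (camera adjusted p = 8.64e-17, adjusted p = 0.0637 with an estimated correlation); Car9 rose by 1.76 ± 0.13 and Ndrg1 by 1.48 ± 0.16. For the metal and iron list, the set had 8 higher, 0 lower and 2 not called of 10 tested genes (8 higher and 0 lower adjusted over the list alone). The list median was 1.00 (camera adjusted p = 1.25e-06, adjusted p = 0.0193 with an estimated correlation). For the NRF2 list of antioxidant genes, the set had 5 higher, 0 lower and 9 not called of 14 tested genes (8 higher and 1 lower adjusted over the list alone). Over these genes, the median was 0.29 (camera adjusted p = 6.08e-05, adjusted p = 0.0266 with an estimated correlation), with Gclc at 0.94 ± 0.14. For the NF-kB and inflammatory list, the set had 8 higher, 1 lower and 7 not called of 16 tested genes (9 higher and 1 lower adjusted over the list alone). The median of these genes was 0.41 (camera adjusted p = 2.01e-04, adjusted p = 0.0266 with an estimated correlation), with Tnfaip3 at 1.14 ± 0.11. The lysosome and autophagy list also had a higher median: it had 15 higher, 0 lower and 4 not called of 19 tested genes (18 higher and 0 lower adjusted over the list alone). Across the list, the median was 0.52 (camera adjusted p = 4.00e-11, adjusted p = 0.0706 with an estimated correlation), with Sqstm1 at 1.26 ± 0.13 and Grn at 0.86 ± 0.13. For the integrin and focal adhesion list, the set had 9 higher, 0 lower and 15 not called of 24 tested genes (9 higher and 0 lower adjusted over the list alone). Its median was 0.24 (camera adjusted p = 2.60e-04, adjusted p = 0.0463 with an estimated correlation), with Vcl at 0.59 ± 0.10.

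The list of YAP targets and contractile genes had a higher median: it had 10 higher, 0 lower and 9 not called of 19 tested genes (10 higher and 0 lower adjusted over the list alone). Their log2 median was 0.45 (camera adjusted p = 1.88e-05, adjusted p = 0.122 with an estimated correlation), with Acta2 at 1.32 ± 0.16 and F3 at 1.46 ± 0.13. Lists with a lower median included cholesterol synthesis: it had 0 higher, 12 lower and 7 not called of 19 tested genes (0 higher and 14 lower adjusted over the list alone). Among them, the median was -0.44 (camera adjusted p = 5.27e-07, adjusted p = 0.0463 with an estimated correlation), with Sqle at -0.61 ± 0.10. For replication-dependent histones, the set had 0 higher, 19 lower and 27 not called of 46 tested genes (1 higher and 24 lower adjusted over the list alone). As a list, the median was -0.92 (camera adjusted p = 8.03e-09, adjusted p = 0.241 with an estimated correlation). For chondrocyte markers, the set had 0 higher, 4 lower and 3 not called of 7 tested genes (0 higher and 6 lower adjusted over the list alone). The log2 median was -0.53 (camera adjusted p = 4.00e-04, adjusted p = 0.106 with an estimated correlation), with Col11a2 at -0.87 ± 0.14. The cell cycle list was not called: it had 0 higher, 1 lower and 32 not called of 33 tested genes (0 higher and 1 lower adjusted over the list alone). The list median was -0.11 (camera adjusted p = 0.198, adjusted p = 0.527 with an estimated correlation). The immediate early and handling list, which holds Atf3, was called higher: it had 9 higher, 3 lower and 7 not called of 19 tested genes (10 higher and 3 lower adjusted over the list alone). Over these genes, the median was 0.46 (camera adjusted p = 0.0095, adjusted p = 0.0609 with an estimated correlation). The mitochondrially encoded list was called with a lower median: it had 0 higher, 1 lower and 7 not called of 8 tested genes (0 higher and 2 lower adjusted over the list alone). The median of these genes was -0.87 (camera adjusted p = 0.0032, adjusted p = 0.34 with an estimated correlation). Of the 31 tested lists, 17 were called here, and 5 held with an estimated correlation: NF-kB, NRF2, integrins, cholesterol synthesis and metal and iron response.

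**Figure D2:**
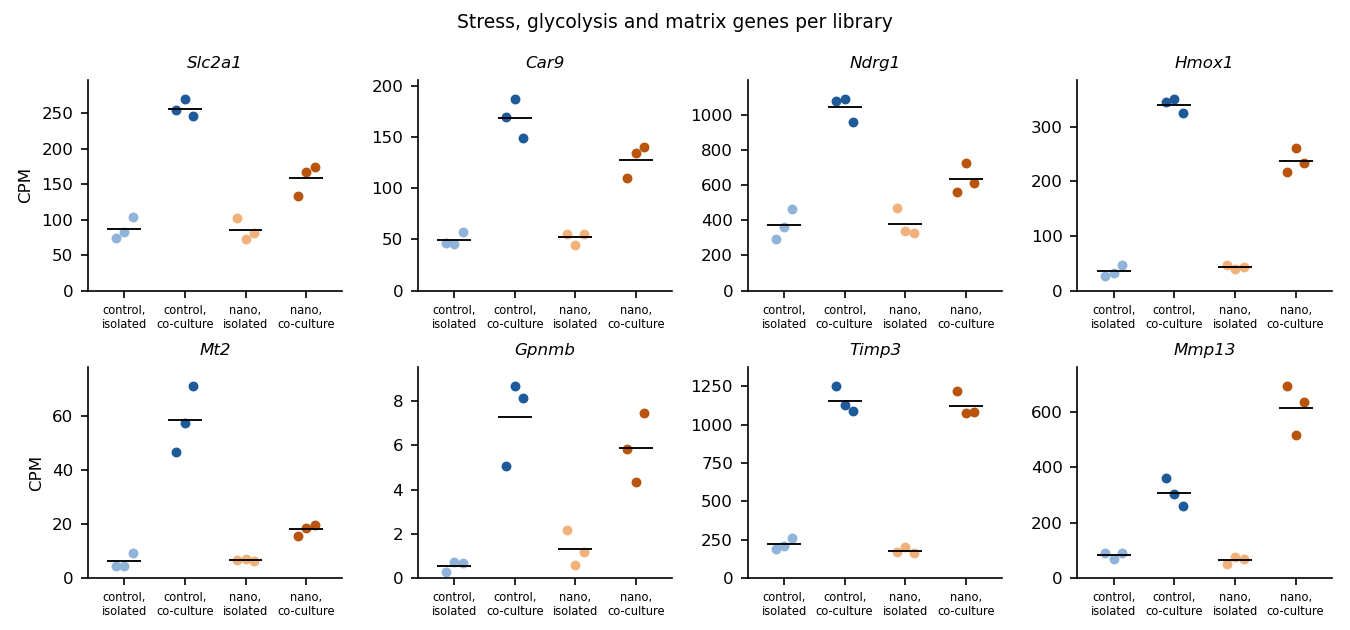
CPM in each library (points) and group mean (line) of stress, hypoxia and matrix genes in the 4 groups. Hmox1 averaged 35.6 CPM in isolated cells on control titanium and 341 CPM in co-culture on control titanium.

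Genes of osteoblast differentiation moved in both directions on control titanium. The osteoblast differentiation and mineralisation list had 2 higher, 9 lower and 15 not called of 26 tested genes (2 higher and 9 lower adjusted over the list alone). Across the list, the median was -0.20 (camera adjusted p = 0.0022, adjusted p = 0.154 with an estimated correlation). Besides Smpd3, the phosphatase gene Phospho1 was lower at -0.88 ± 0.14 (adjusted p = 3.54e-04), Runx2 at -0.37 ± 0.12 (adjusted p = 0.036), Ibsp at -0.55 ± 0.14 (adjusted p = 0.0124) and Dmp1 at -1.06 ± 0.27 (adjusted p = 0.01). The osteopontin gene Spp1 was higher at 0.69 ± 0.12 (adjusted p = 5.92e-04). Sp7 at -0.15 ± 0.10, Alpl at 0.14 ± 0.13, Bglap at -0.04 ± 0.17, Bglap2 at 0.07 ± 0.16, Col1a1 at -0.18 ± 0.11 and Phex at -0.39 ± 0.21 were not called, though Sp7 was when GC-adjusted (-0.23, adjusted p = 0.0371). Tnfrsf11b, which encodes the RANKL decoy osteoprotegerin, was lower at -0.67 ± 0.11 (adjusted p = 4.57e-04). RANKL itself (Tnfsf11) had 0 counts in each group, which allows up to 0.137 CPM over the isolated libraries on control titanium and 0.130 over the co-culture libraries there, from a limit of 3 counts.

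With osteoclasts on nanotopography, 7890 of 13340 tested genes (3835 higher and 4055 lower) were called, 1397 higher and 1690 lower by at least 2-fold. The comparison asks how osteoblasts that share medium with osteoclasts differ from isolated ones on the modified surface. Mmp13 went from 64.1 ± 13.0 to 615 ± 90.5 CPM (log2 fold change 3.26 ± 0.17, edgeR adjusted p = 2.85e-10, GC-adjusted 2.65). Hmox1 rose by 2.44 ± 0.15 (adjusted p = 2.00e-09, GC-adjusted 2.98). Smpd3 was lower at -2.38 ± 0.10 and Phospho1 at -2.36 ± 0.15, with adjusted p = 4.27e-11 and 3.98e-09; the GC-adjusted values were -1.82 and -1.12. Spp1 was higher at 1.77 ± 0.12 (adjusted p = 9.40e-09, GC-adjusted 1.34). The GC-adjusted count was 5280 (2526 higher and 2754 lower), and 3565 genes were called in both with the same direction, 317 with opposite ones. Of the 30 tested genes named for this comparison, 27 to 30 stayed on their side of the threshold when 1 library was left out, the fewest without isolated nano replicate 1. Calls were lost for Bglap (-0.40, adjusted p = 0.0819 without isolated nano replicate 2), Ezh2 (0.17, adjusted p = 0.224 without coculture nano replicate 1) and Phex (0.50, adjusted p = 0.104 without isolated nano replicate 1). A call was gained for Ibsp (-0.41, adjusted p = 0.0334 without isolated nano replicate 1). Each log2 fold change and p is given without the library that moved the p most.

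Ptgs2 rose by 2.98 ± 0.12, Timp3 by 2.65 ± 0.13 and Ddit3 by 2.64 ± 0.12, with GC-adjusted values of 2.14, 2.41 and 2.47. Vegfa rose by 1.22 ± 0.12 and Car9 by 1.30 ± 0.13 (GC-adjusted 1.41 and 1.86). The genes with the highest fold changes were near absent from isolated cells. Clec5a had 0 counts there and 114 in co-culture, at least 32.9-fold higher against 3 counts over the group. Itga4, Dock2 and the osteoclast marker Atp6v0d2 were at least 31.2-fold, 27.4-fold and 21.1-fold higher. Lpl had 1 count in isolated cells and 338 in co-culture, a ratio of 293 (95% counting interval 52.2 to 11599). Galnt2 had 148 counts in isolated cells and 0 in co-culture, at least 56.9-fold lower. Scand1 had -6.43 ± 0.25 and H1fx -6.53 ± 0.29 (GC-adjusted -4.15 and -4.06).

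For the osteoblast list on nanotopography, the set had 3 higher, 14 lower and 9 not called of 26 tested genes (3 higher and 14 lower adjusted over the list alone). Its median was -0.45 (camera adjusted p = 0.018, adjusted p = 0.285 with an estimated correlation); GC-adjusted, it was -0.08 (camera adjusted p = 0.339, adjusted p = 0.604 with an estimated correlation). The bone gene Ifitm5 was lower at -2.90 ± 0.22 (GC-adjusted -2.02). Sp7 at -0.61 ± 0.10 (adjusted p = 7.43e-05) and Col1a1 at -0.95 ± 0.11 (adjusted p = 2.82e-06) were lower, and their GC-adjusted values of -0.06 and -0.14 were not called (adjusted p = 0.559 and 0.188). Alpl was lower at -0.54 ± 0.13 (adjusted p = 0.0022) and Bglap at -0.50 ± 0.18 (adjusted p = 0.0231), but both turned positive when GC-adjusted, at 0.23 (adjusted p = 0.0298) and 0.41 (adjusted p = 0.133). Phex was higher at 0.68 ± 0.24 (adjusted p = 0.0188; GC-adjusted -0.23, adjusted p = 0.362). Tnfrsf11b was lower at -0.46 ± 0.11 (adjusted p = 0.0022; GC-adjusted -0.95, adjusted p = 5.26e-09). Runx2 at 0.02 ± 0.12, Bglap2 at -0.12 ± 0.17, Ibsp at -0.29 ± 0.14 and Dmp1 at -0.37 ± 0.27 were not called. GC-adjusted, Ibsp was lower at -0.56 (adjusted p = 0.0012) and Bglap2 higher at 0.86 (adjusted p = 0.0262), while Runx2 at 0.01 and Dmp1 at -0.17 were not called.

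**Figure D3:**
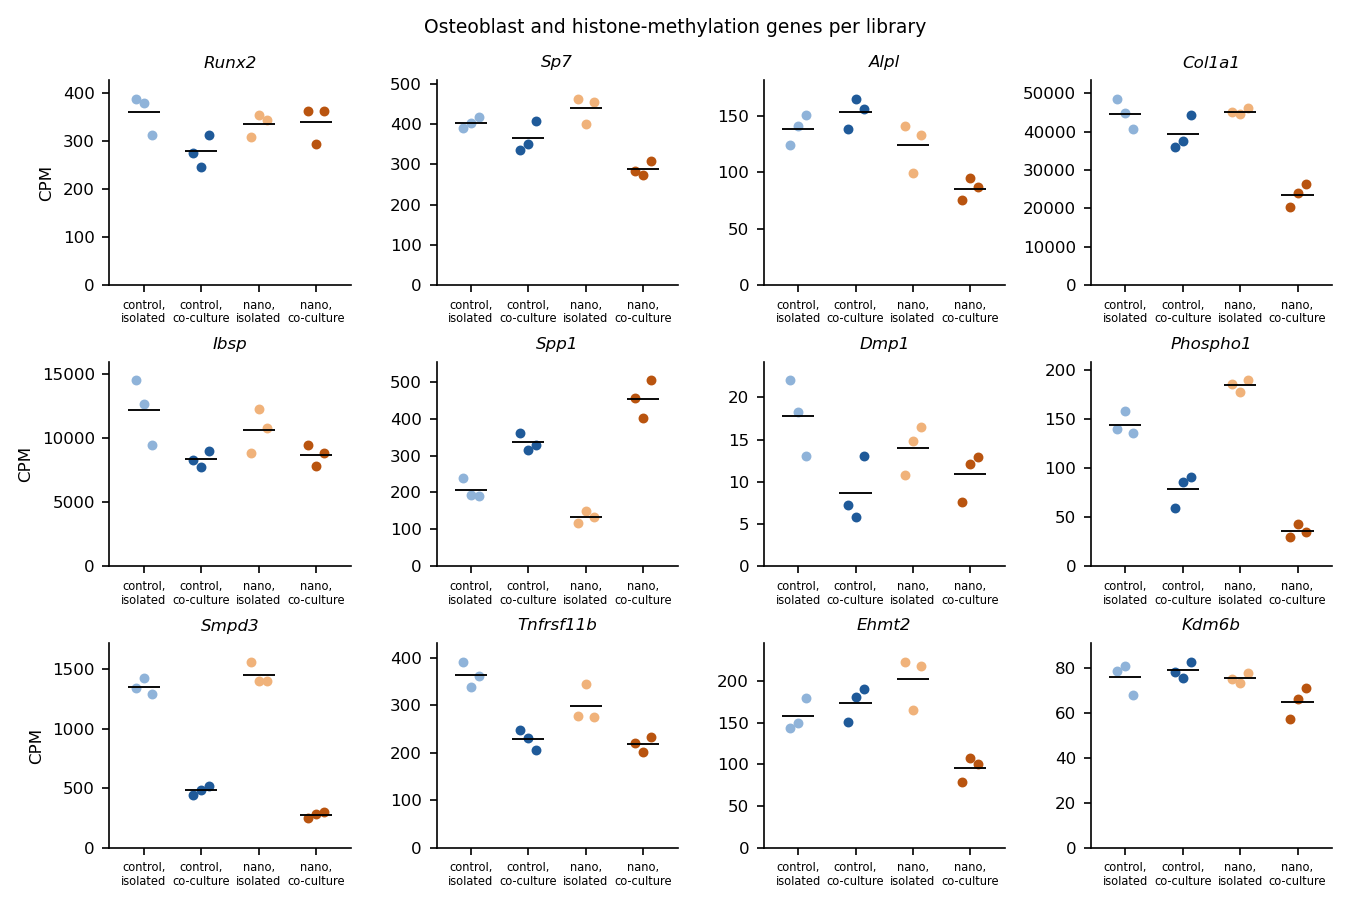
CPM in each library (points) and group mean (line) of osteoblast and histone-methylation genes in the 4 groups. Smpd3 averaged 1453 CPM in isolated cells on nanotopography and 279 CPM in co-culture there.

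Of the other lists on nanotopography, cholesterol synthesis had a lower median: it had 0 higher, 14 lower and 5 not called of 19 tested genes (0 higher and 14 lower adjusted over the list alone). Their log2 median was -0.56 (camera adjusted p = 1.59e-04, adjusted p = 0.209 with an estimated correlation), and GC-adjusted it was -0.68 (camera adjusted p = 1.23e-09, adjusted p = 0.0277 with an estimated correlation), with Mvk at -2.21 ± 0.19 (GC-adjusted -1.45). For nuclear-encoded oxidative phosphorylation genes, the set had 1 higher, 21 lower and 8 not called of 30 tested genes (3 higher and 23 lower adjusted over the list alone). Among them, the median was -0.64 (camera adjusted p = 1.59e-04, adjusted p = 0.313 with an estimated correlation); GC-adjusted, it was -0.41 (camera adjusted p = 3.77e-05, adjusted p = 0.156 with an estimated correlation), with Uqcrq at -2.65 ± 0.19 (GC-adjusted -2.43). For ribosomal protein genes, the set had 3 higher, 48 lower and 20 not called of 71 tested genes (4 higher and 49 lower adjusted over the list alone). As a list, the median was -0.71 (camera adjusted p = 3.34e-08, adjusted p = 0.209 with an estimated correlation); GC-adjusted, it was -0.29 (camera adjusted p = 1.17e-05, adjusted p = 0.0277 with an estimated correlation). For replication-dependent histones, the set had 0 higher, 43 lower and 3 not called of 46 tested genes (0 higher and 44 lower adjusted over the list alone). The log2 median was -3.46 (camera adjusted p = 1.91e-15, adjusted p = 0.285 with an estimated correlation); GC-adjusted, it was -2.45 (camera adjusted p = 5.48e-18, adjusted p = 0.0816 with an estimated correlation). The hypoxia list was called only after adjustment: it had 13 higher, 6 lower and 8 not called of 27 tested genes (13 higher and 7 lower adjusted over the list alone). The list median was 0.33 (camera adjusted p = 0.185, adjusted p = 0.765 with an estimated correlation), and GC-adjusted 0.40 (camera adjusted p = 3.77e-05, adjusted p = 0.182 with an estimated correlation). So were the immediate early and handling list, higher, and mitochondrially encoded transcripts, lower. As measured, the first had 10 higher, 7 lower and 2 not called of 19 tested genes (10 higher and 7 lower adjusted over the list alone). Over these genes, the median was 0.46 (camera adjusted p = 0.662, adjusted p = 0.765 with an estimated correlation), and GC-adjusted 0.60 (camera adjusted p = 0.0015, adjusted p = 0.0952 with an estimated correlation). As measured, the second had 1 higher, 0 lower and 7 not called of 8 tested genes (1 higher and 0 lower adjusted over the list alone). The median of these genes was 0.05 (camera adjusted p = 0.77, adjusted p = 0.899 with an estimated correlation), and GC-adjusted -0.96 (camera adjusted p = 6.46e-04, adjusted p = 0.116 with an estimated correlation). Among called genes, 636 were higher and 595 lower with osteoclasts on both surfaces, against 422 and 355 under independence, and 423 moved in opposite directions (782 under independence). The GC-adjusted counts were 1002, 766 and 221.

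Without osteoclasts, 1347 of 13340 tested genes (597 higher and 750 lower) differed between the surfaces; the comparison asks what the surface does to osteoblasts alone. Spp1 was lower at -0.64 ± 0.12 (edgeR adjusted p = 0.0116, GC-adjusted -0.41) and Phex at -1.19 ± 0.23 (adjusted p = 0.0117, GC-adjusted -0.72). The tropomyosin gene Tpm2 was higher at 0.74 ± 0.14 (adjusted p = 0.0094, GC-adjusted 0.53), and so was the chaperone gene Calr at 0.74 ± 0.13 (adjusted p = 0.0077, GC-adjusted 0.66). The amino acid stress genes Chac1 and Trib3 were lower at -0.97 ± 0.20 and -0.89 ± 0.19 (GC-adjusted -1.24 and -1.15). The GC-adjusted count was 757 (496 higher and 261 lower), and 469 genes were called in both with the same direction. The number of calls depended on single libraries: it was 2 without isolated control replicate 1, 46 without isolated control replicate 2, 2152 without isolated control replicate 3, 67 without isolated nano replicate 1, 2912 without isolated nano replicate 2, 3 without isolated nano replicate 3, 856 without coculture nano replicate 3. Of the 19 tested genes named for this comparison, 7 to 19 stayed on their side of the threshold when 1 library was left out, the fewest without isolated control replicate 1 or isolated nano replicate 3. Calls were lost for Bmp8a (-1.59, adjusted p = 0.0998 without isolated nano replicate 3), Calr (0.73, adjusted p = 0.0746 without isolated nano replicate 3), Chac1 (-0.92, adjusted p = 0.0777 without isolated nano replicate 1), Clcn3 (-1.29, adjusted p = 0.0746 without isolated nano replicate 3), Hist1h1e (1.25, adjusted p = 0.0655 without isolated nano replicate 3), Kif20a (0.49, adjusted p = 0.115 without isolated nano replicate 3) and Mcm3 (0.51, adjusted p = 0.115 without isolated nano replicate 3). They were also lost for Ndufa9 (0.64, adjusted p = 0.0737 without isolated nano replicate 3), Phex (-1.07, adjusted p = 0.0998 without isolated nano replicate 3), Spp1 (-0.63, adjusted p = 0.086 without isolated nano replicate 3), Tpm2 (0.74, adjusted p = 0.0746 without isolated nano replicate 3) and Trib3 (-0.76, adjusted p = 0.115 without isolated nano replicate 3). A call was gained for Tnfrsf11b (-0.41, adjusted p = 0.0171 without isolated nano replicate 2). Each log2 fold change and p is given without the library that moved the p most.

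The genes with the largest increases were replication-dependent histones, such as Hist1h2bm at 1.56 ± 0.19 and Hist1h1e at 1.36 ± 0.23 (GC-adjusted 1.25 and 1.24). They moved with the share of Gm26917 and Gm42418 given above, and whether library composition sets them was not tested. Hist1h1e went from 189 ± 0.792 to 487 ± 87.3 CPM. For that list, the set had 32 higher, 0 lower and 14 not called of 46 tested genes (43 higher and 0 lower adjusted over the list alone). Across the list, the median was 1.17 (camera adjusted p = 1.92e-24, adjusted p = 0.497 with an estimated correlation); GC-adjusted, it was 0.92 (camera adjusted p = 4.03e-25, adjusted p = 0.142 with an estimated correlation). For the cell cycle list, the set had 8 higher, 0 lower and 25 not called of 33 tested genes (13 higher and 0 lower adjusted over the list alone). Its median was 0.32 (camera adjusted p = 0.0011, adjusted p = 0.646 with an estimated correlation), with Mcm3 at 0.59 ± 0.13 and Kif20a at 0.52 ± 0.12 (GC-adjusted 0.45 and 0.52); GC-adjusted, it was 0.29 (camera adjusted p = 1.32e-06, adjusted p = 0.213 with an estimated correlation). For oxidative phosphorylation, the set had 9 higher, 0 lower and 21 not called of 30 tested genes (10 higher and 0 lower adjusted over the list alone). Their log2 median was 0.26 (camera adjusted p = 0.0018, adjusted p = 0.646 with an estimated correlation), with Ndufa9 at 0.65 ± 0.11 (GC-adjusted 0.66); GC-adjusted, it was 0.20 (camera adjusted p = 3.36e-04, adjusted p = 0.287 with an estimated correlation). For the YAP and contractile list, the set had 4 higher, 0 lower and 15 not called of 19 tested genes (9 higher and 1 lower adjusted over the list alone). Among them, the median was 0.29 (camera adjusted p = 0.0192, adjusted p = 0.646 with an estimated correlation); GC-adjusted, it was 0.01 (camera adjusted p = 0.47, adjusted p = 0.664 with an estimated correlation), and the call was lost without isolated control replicate 1. The histone, cell cycle and oxidative phosphorylation lists stayed called in each of the 12 runs that left out 1 library. The lowest fold changes included Bmp8a at -1.47 ± 0.32 and Clcn3 at -1.32 ± 0.24 (GC-adjusted -1.72 and -0.92). The osteoblast list was called only after adjustment: it had 0 higher, 4 lower and 22 not called of 26 tested genes (0 higher and 4 lower adjusted over the list alone). As a list, the median was -0.07 (camera adjusted p = 0.469, adjusted p = 0.745 with an estimated correlation), and GC-adjusted -0.17 (camera adjusted p = 3.63e-05, adjusted p = 0.213 with an estimated correlation). The immediate early and handling list and mitochondrially encoded transcripts, also not called as measured, had GC-adjusted medians of -0.23 and 0.37 (camera adjusted p = 0.0011 and 0.0375), but neither was called with an estimated correlation (adjusted p = 0.142 and 0.543). Runx2 at -0.10 ± 0.12, Sp7 at 0.12 ± 0.10, Alpl at -0.16 ± 0.13, Col1a1 at 0.02 ± 0.11, Ibsp at -0.20 ± 0.14 and Tnfrsf11b at -0.28 ± 0.11 were not called. GC-adjusted, Alpl was lower at -0.39 (adjusted p = 0.0087), while Runx2 at -0.14, Sp7 at -0.07, Col1a1 at -0.21, Ibsp at -0.06 and Tnfrsf11b at -0.02 were not called.

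With osteoclasts, 5602 of 13340 tested genes (2485 higher and 3117 lower) differed between the surfaces; the comparison asks whether nanotopography changes the state of osteoblasts that share medium with osteoclasts. Mt2 was lower on nanotopography, at -1.69 ± 0.19 (edgeR adjusted p = 1.65e-05, GC-adjusted -1.15). Mmp13 was higher at 0.99 ± 0.15 (adjusted p = 1.74e-04, GC-adjusted 0.56). Ifitm5 was lower at -2.00 ± 0.23 (adjusted p = 1.71e-05, GC-adjusted -1.42) and Smpd3 at -0.79 ± 0.10 (adjusted p = 3.42e-05, GC-adjusted -0.34). Alpl at -0.84 ± 0.13, Bglap at -0.82 ± 0.18 and Col1a1 at -0.75 ± 0.11 were lower, and their GC-adjusted values were -0.25, -0.26 and -0.14 (adjusted p = 0.0363, 0.396 and 0.255). Sp7 was lower at -0.34 ± 0.10 and turned positive, at 0.10, when GC-adjusted (adjusted p = 0.418). Runx2 at 0.29 ± 0.12 was not called (adjusted p = 0.0602), but was when GC-adjusted, at 0.31 (adjusted p = 0.0301). The GC-adjusted count was 2357 (941 higher and 1416 lower), and 1543 genes were called in both with the same direction, 47 with opposite ones. The count was 3271 without coculture nano replicate 1. Of the 19 tested genes named for this comparison, 17 to 19 stayed on their side of the threshold when 1 library was left out, the fewest without coculture control replicate 3. Calls were lost for Sp7 (-0.26, adjusted p = 0.0699 without coculture control replicate 3). A call was gained for Runx2 (0.38, adjusted p = 0.023 without coculture nano replicate 2). Each log2 fold change and p is given without the library that moved the p most.

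The hypoxia and glycolysis list had a lower median on nanotopography among co-cultures: it had 0 higher, 16 lower and 11 not called of 27 tested genes (0 higher and 16 lower adjusted over the list alone). The log2 median was -0.39 (camera adjusted p = 1.83e-05, adjusted p = 0.573 with an estimated correlation); GC-adjusted, it was -0.24 (camera adjusted p = 6.85e-04, adjusted p = 0.834 with an estimated correlation), with Pfkl at -1.23 ± 0.17 and Tpi1 at -1.02 ± 0.16 (GC-adjusted -0.65 and -0.61). For ribosomal protein genes, the set had 3 higher, 36 lower and 32 not called of 71 tested genes (3 higher and 36 lower adjusted over the list alone). The list median was -0.47 (camera adjusted p = 1.02e-06, adjusted p = 0.318 with an estimated correlation). GC-adjusted, it was -0.25 (camera adjusted p = 9.79e-06, adjusted p = 0.0372 with an estimated correlation). Rplp0 had -2.24 ± 0.17 and Rps7 -1.82 ± 0.15 (GC-adjusted -1.86 and -1.71), with the uncertainty given above for Rps2. For oxidative phosphorylation, the set had 1 higher, 16 lower and 13 not called of 30 tested genes (1 higher and 16 lower adjusted over the list alone). Over these genes, the median was -0.46 (camera adjusted p = 0.0064, adjusted p = 0.573 with an estimated correlation); GC-adjusted, it was -0.22 (camera adjusted p = 0.0037, adjusted p = 0.834 with an estimated correlation), with Uqcrq at -1.89 ± 0.20 (GC-adjusted -1.71). For the osteoblast list, the set had 3 higher, 14 lower and 9 not called of 26 tested genes (4 higher and 14 lower adjusted over the list alone). The median of these genes was -0.37 (camera adjusted p = 0.0128, adjusted p = 0.573 with an estimated correlation); GC-adjusted, it was -0.12 (camera adjusted p = 0.585, adjusted p = 0.95 with an estimated correlation). The Wnt list had a lower median, near the threshold: it had 2 higher, 11 lower and 8 not called of 21 tested genes (2 higher and 11 lower adjusted over the list alone). Across the list, the median was -0.35 (camera adjusted p = 0.0494, adjusted p = 0.573 with an estimated correlation), with Axin2 at -1.08 ± 0.14 and Tcf7 at -0.64 ± 0.10 (GC-adjusted -0.68 and -0.34); the call was lost without coculture control replicate 1 and without coculture nano replicate 2, and GC-adjusted it was -0.05 (camera adjusted p = 0.779, adjusted p = 0.95 with an estimated correlation). The immediate early and handling list had a lower median: it had 1 higher, 9 lower and 9 not called of 19 tested genes (1 higher and 9 lower adjusted over the list alone). Its median was -0.44 (camera adjusted p = 0.0077, adjusted p = 0.29 with an estimated correlation), and GC-adjusted 0.01 (camera adjusted p = 0.938, adjusted p = 0.966 with an estimated correlation). The mitochondrially encoded list was called with a higher median, though 0 of its members passed over the list alone: it had 1 higher, 0 lower and 7 not called of 8 tested genes (0 higher and 0 lower adjusted over the list alone). Their log2 median was 0.63 (camera adjusted p = 0.0257, adjusted p = 0.586 with an estimated correlation), and GC-adjusted -0.22 (camera adjusted p = 0.872, adjusted p = 0.966 with an estimated correlation). That call was lost without coculture control replicate 1, coculture control replicate 2 or coculture nano replicate 1. Lpl was higher at 3.37 ± 0.42 and Clec5a at 4.51 ± 0.67, while Sdsl was lower at -3.19 ± 0.48 (GC-adjusted 3.08, 3.96 and -2.37). Of 37 macrophage and osteoclast markers, 10 chosen after their values were seen, by a cut that 9 of them reached on nanotopography alone and 0 on control titanium alone, had a summed CPM of 6.18 to 20.2 against 0.109 to 3.10. Others went the other way, such as Clcn7 with 800 counts on control titanium and 510 on nanotopography and Tcirg1 with 340 and 219. The osteoclast marker list was not called: it had 2 higher, 2 lower and 4 not called of 8 tested genes (2 higher and 2 lower adjusted over the list alone). Among them, the median was -0.19 (camera adjusted p = 0.882, adjusted p = 0.926 with an estimated correlation), and GC-adjusted 0.16 (camera adjusted p = 0.217, adjusted p = 0.834 with an estimated correlation). Of the genes called for the surface, 879 moved one way without and the other way with osteoclasts (279 under independence), 217 when GC-adjusted (71.1 under independence). The comparisons share no libraries, but their trends with GC content ran in opposite directions. Genes under 40% GC had medians of -0.57 without and 0.67 with osteoclasts, and genes over 60% GC 0.29 and -0.92. Opposite trends by themselves raise the number of opposite moves, so the measured excess over independence cannot be read as a reversed surface effect.

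**Figure D4:**
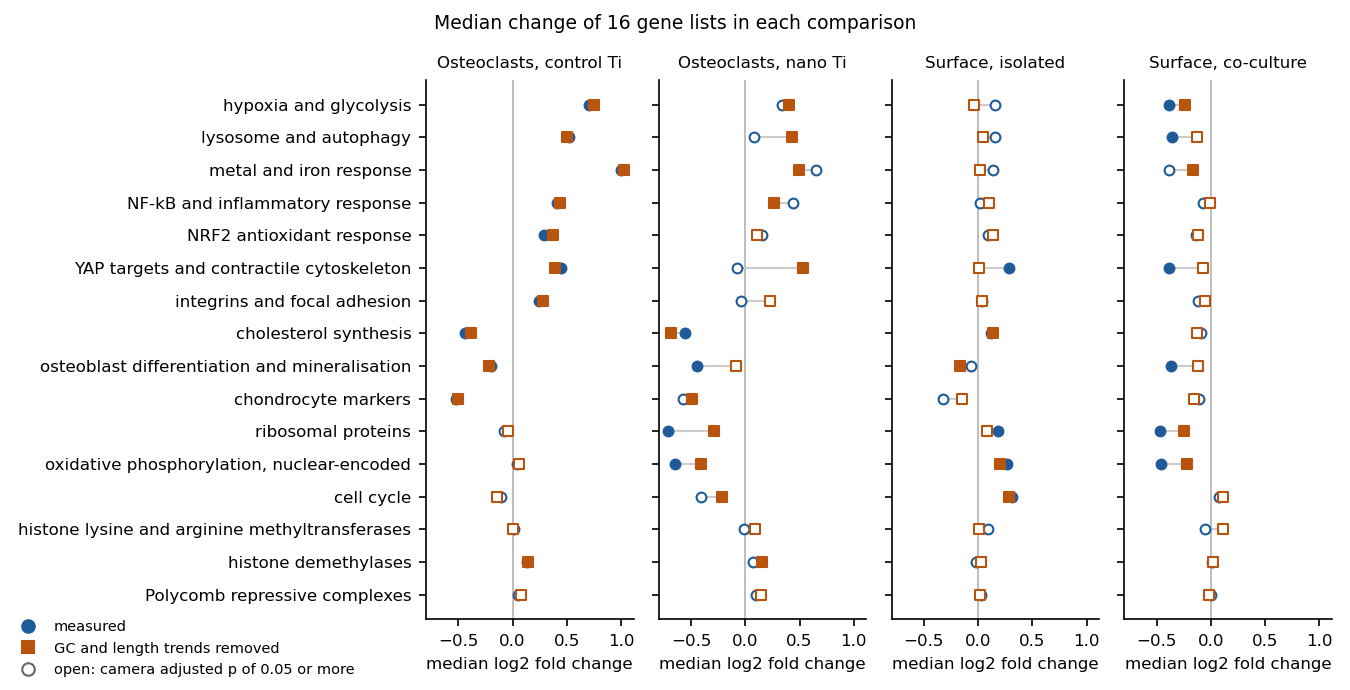
Median log2 fold change (horizontal axis) of 16 gene lists in 4 comparisons, as measured (circles) and GC-adjusted (squares), with filled symbols where camera gave an adjusted p under 0.05. Hypoxia and glycolysis genes had medians of 0.70 with osteoclasts on control titanium and -0.39 for the surface with osteoclasts.

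The interaction asks whether the osteoclast effect differed between the surfaces, and 6384 of 13340 tested genes (2999 higher and 3385 lower) were called. The osteoclast response of Ifitm5 was more negative on nanotopography by -2.29 ± 0.29 (edgeR adjusted p = 6.05e-05, GC-adjusted -1.45), and that of Mt2 was smaller, at -1.86 ± 0.33 (adjusted p = 3.91e-04, GC-adjusted -1.08). The response of Spp1 was larger on nanotopography by 1.07 ± 0.17 (adjusted p = 1.97e-04, GC-adjusted 0.52, adjusted p = 0.0051), and that of Mmp13 by 1.35 ± 0.22 (adjusted p = 2.56e-04, GC-adjusted 0.60). Smpd3 at -0.90 ± 0.14 and Phospho1 at -1.48 ± 0.21 were no longer called when GC-adjusted, at -0.27 and -0.30 (adjusted p = 0.0702 and 0.161). Sp7 at -0.46 ± 0.14, Alpl at -0.68 ± 0.19 and Col1a1 at -0.76 ± 0.16 were called, and turned positive, at 0.17, 0.13 and 0.08, when GC-adjusted (adjusted p = 0.322, 0.44 and 0.677). Runx2 at 0.39 ± 0.17 was not called, with a GC-adjusted 0.45 (adjusted p = 0.0253). Hmox1 had -0.83 ± 0.20 and Pfkl -1.64 ± 0.24 (GC-adjusted -0.25 and -0.86, adjusted p = 0.233 and 4.28e-04). The GC-adjusted count was 2789 (1082 higher and 1707 lower), and 1841 genes were called in both with the same direction, 100 with opposite ones. Of the 19 tested genes named for this comparison, 18 to 19 stayed on their side of the threshold when 1 library was left out, the fewest without coculture control replicate 3, coculture nano replicate 2, isolated control replicate 3 or isolated nano replicate 2. A call was gained for Runx2 (0.49, adjusted p = 0.0221 without isolated control replicate 3). Each log2 fold change and p is given without the library that moved the p most.

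By lists, hypoxia and glycolysis had 0 higher, 14 lower and 13 not called of 27 tested genes (0 higher and 14 lower adjusted over the list alone). As a list, the median was -0.55 (camera adjusted p = 0.0027, adjusted p = 0.642 with an estimated correlation); GC-adjusted, it was -0.18 (camera adjusted p = 0.0535, adjusted p = 0.796 with an estimated correlation). For oxidative phosphorylation, the set had 1 higher, 16 lower and 13 not called of 30 tested genes (1 higher and 16 lower adjusted over the list alone). The log2 median was -0.79 (camera adjusted p = 0.0022, adjusted p = 0.642 with an estimated correlation); GC-adjusted, it was -0.39 (camera adjusted p = 3.29e-05, adjusted p = 0.476 with an estimated correlation), with Uqcrq at -1.95 ± 0.26 (GC-adjusted -1.70). For replication-dependent histones, the set had 0 higher, 33 lower and 13 not called of 46 tested genes (0 higher and 35 lower adjusted over the list alone). The list median was -2.31 (camera adjusted p = 1.93e-08, adjusted p = 0.642 with an estimated correlation); GC-adjusted, it was -1.33 (camera adjusted p = 2.20e-08, adjusted p = 0.476 with an estimated correlation), with Hist2h2ac at -4.19 ± 0.50 (GC-adjusted -2.92). For ribosomal proteins, the set had 4 higher, 40 lower and 27 not called of 71 tested genes (4 higher and 41 lower adjusted over the list alone). Over these genes, the median was -0.69 (camera adjusted p = 1.54e-06, adjusted p = 0.642 with an estimated correlation). GC-adjusted, it was -0.32 (camera adjusted p = 2.23e-05, adjusted p = 0.0635 with an estimated correlation). Rps16 had -3.42 ± 0.46 (GC-adjusted -3.11), with the uncertainty given above for Rps2. For the lysosome list, the set had 1 higher, 12 lower and 6 not called of 19 tested genes (1 higher and 13 lower adjusted over the list alone). The median of these genes was -0.58 (camera adjusted p = 0.0086, adjusted p = 0.642 with an estimated correlation); GC-adjusted, it was -0.24 (camera adjusted p = 0.195, adjusted p = 0.841 with an estimated correlation), with Grn at -1.24 ± 0.18 (GC-adjusted -0.46). For the YAP list, the set had 1 higher, 12 lower and 6 not called of 19 tested genes (2 higher and 12 lower adjusted over the list alone). Across the list, the median was -0.71 (camera adjusted p = 0.006, adjusted p = 0.642 with an estimated correlation); GC-adjusted, it was -0.13 (camera adjusted p = 0.706, adjusted p = 0.841 with an estimated correlation), with Srf at -1.39 ± 0.20 (GC-adjusted -0.07, adjusted p = 0.767). For the osteoblast list, the set had 5 higher, 11 lower and 10 not called of 26 tested genes (7 higher and 12 lower adjusted over the list alone). Its median was -0.36 (camera adjusted p = 0.327, adjusted p = 0.721 with an estimated correlation); GC-adjusted, it was 0.14 (camera adjusted p = 0.195, adjusted p = 0.782 with an estimated correlation).

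Attenuation was asked of all 6301 genes called in the osteoclast effect averaged over surfaces (3033 higher and 3268 lower). The interaction of each gene was signed so that a negative value means a smaller osteoclast effect on nanotopography. The median was 0.64 and called by fry, and 19.3% of the genes had a smaller effect on nanotopography. Genes higher with osteoclasts had a median of 0.48 and genes lower with them one of 0.78, GC-adjusted 0.08 and 0.25. GC-adjusted, the median over 5491 genes was 0.16 and called by fry, with 35.9% smaller on nanotopography. Fry called the shift in 22 of the 22 settings run, which share most of their libraries. Fry also called a simulated equal effect with a median of -0.02. The simulation gave each group the same noise, whereas a wider spread of changes on nanotopography from any source favours a positive median. In the averaged surface effect, 528 genes were called (60 higher and 468 lower), and 570 when GC-adjusted (234 higher and 336 lower). The count was 221 without coculture control replicate 2, 348 without coculture control replicate 3, 294 without coculture nano replicate 1, 291 without isolated control replicate 2, 302 without isolated control replicate 3, 318 without isolated nano replicate 2, 284 without isolated nano replicate 3.

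The series title names histone methylation, so genes of that machinery were read as transcripts; no histone mark was measured. With osteoclasts on control titanium the demethylase genes Kdm3a, Jmjd6 and Kdm4b were higher by 0.85 ± 0.10, 0.74 ± 0.12 and 0.67 ± 0.16, with adjusted p = 1.39e-05, 3.49e-04 and 0.0077. The demethylase list had 5 higher, 0 lower and 17 not called of 22 tested genes (5 higher and 0 lower adjusted over the list alone). Their log2 median was 0.13 (camera adjusted p = 0.0095, adjusted p = 0.0609 with an estimated correlation). The methyltransferase genes Ezh1 and Smyd3 were higher at 0.69 ± 0.11 and 0.87 ± 0.17, and Setd7 lower at -0.34 ± 0.10 (adjusted p = 0.0281). The methyltransferase list was not called in any of the 5 comparisons between groups, with 3 higher and 2 lower of 34 on control titanium (3 and 1 adjusted over the list alone; adjusted p = 0.59), 11 and 11 on nanotopography (11 and 11 adjusted over the list alone; adjusted p = 0.688) and 10 and 10 in the interaction (10 and 11 adjusted over the list alone; adjusted p = 0.98). Its GC-adjusted medians for the last 2 were 0.09 and 0.13 (adjusted p = 0.143 and 0.204). The Polycomb list on control titanium had 5 higher, 0 lower and 20 not called of 25 tested genes (5 higher and 0 lower adjusted over the list alone). Among them, the median was 0.05 (camera adjusted p = 0.229, adjusted p = 0.285 with an estimated correlation). Ezh2 was not called on control titanium, at 0.00 ± 0.12, and was higher with osteoclasts on nanotopography at 0.29 ± 0.12 (adjusted p = 0.039; GC-adjusted -0.07, adjusted p = 0.539). Ehmt2 was lower with osteoclasts on nanotopography at -1.08 ± 0.14 (adjusted p = 7.79e-06), with an interaction of -1.22 ± 0.20 (adjusted p = 2.54e-04), but its GC-adjusted values were 0.01 and -0.16 (adjusted p = 0.916 and 0.346). Kdm6b was not called with osteoclasts, at 0.05 ± 0.11 on control titanium and -0.22 ± 0.11 on nanotopography, though it was on nanotopography when GC-adjusted, at 0.64 (adjusted p = 1.01e-05). For the surface with osteoclasts Kdm6b was called lower at -0.28 ± 0.11 and higher when GC-adjusted, at 0.33 (edgeR adjusted p = 0.0436 and 0.017). Its interaction of -0.27 ± 0.15 was not called, but the GC-adjusted 0.58 was (adjusted p = 0.0034). These surface and interaction values are not in the counts of named genes. Kdm4b had an interaction of -1.64 ± 0.23 (adjusted p = 9.72e-05; GC-adjusted -0.76, adjusted p = 0.0015).

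Genes of other cell types were counted in the osteoblast libraries. Of the 37 listed macrophage and osteoclast markers, 10 had at most 3 counts over the 6 isolated libraries and at least 10 over the 6 co-culture libraries, a choice made after their values were seen. Their summed CPM in the 3 libraries was 0.109, 2.66 and 3.10 in co-culture on control titanium and 6.18, 14.9 and 20.2 in co-culture on nanotopography, and at most 0.341 in an isolated library. The choice itself keeps the isolated values low. Atp6v0d2 had 0 counts in isolated cells, 7 in co-culture on control titanium and 73 in co-culture on nanotopography, and Ptprc had 0, 2 and 44. The macrophage genes Csf1r and Lyz2 were higher with osteoclasts on nanotopography, at 1.71 ± 0.45 and 2.15 ± 0.42 (adjusted p = 0.0034 and 3.26e-04; GC-adjusted 2.15 and 2.21). The osteoclast protease gene Ctsk, which osteoblast libraries also held, had 3767 counts in isolated cells and 3944 in co-culture on control titanium, and 3092 and 3939 on nanotopography. With fewer than 5 tested members, the macrophage and muscle lists were not tested as sets; 0 of 4 macrophage genes were higher with osteoclasts on control titanium and 3 on nanotopography (0 and 4 adjusted over the list alone), and 1 of 2 muscle genes, Acta1, on control titanium.

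**Figure D5:**
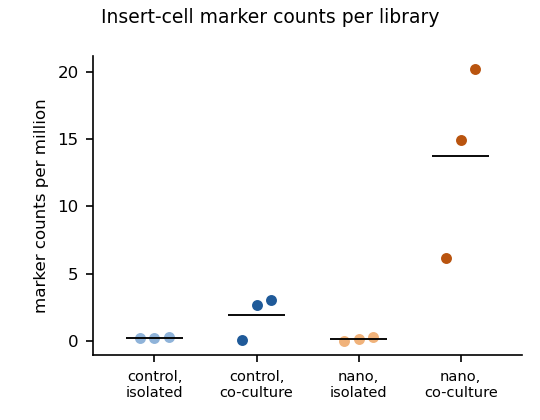
Summed CPM (vertical axis) of 10 macrophage and osteoclast marker genes in each library (points) of the 4 groups. The 3 co-culture libraries on nanotopography sit between 6.18 and 20.2 and the isolated libraries at or below 0.341. The genes were chosen after their values were seen, with at most 3 counts over the 6 isolated libraries and at least 10 in co-culture. Low values in isolated libraries follow from that choice.

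The key genes lie at these positions: Hmox1 (ENSMUSG00000005413.8, chromosome 8, 75093621 to 75100589), Mt2 (ENSMUSG00000031762.7, chromosome 8, 94172664 to 94173568), Slc2a1 (ENSMUSG00000028645.11, chromosome 4, 119108711 to 119137983), Smpd3 (ENSMUSG00000031906.9, chromosome 8, 106252548 to 106337988), Spp1 (ENSMUSG00000029304.14, chromosome 5, 104435118 to 104441050), Mmp13 (ENSMUSG00000050578.10, chromosome 9, 7272514 to 7283331), Galnt2 (ENSMUSG00000089704.9, chromosome 8, 124231391 to 124345724) and Ehmt2 (ENSMUSG00000013787.15, chromosome 17, 34898469 to 34914052).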

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

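The tests of the GC trend and of carry-over from the insert were chosen after the results were seen; the test that left out a library and the regroupings were planned.

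The osteoclast effect differed between the surfaces by a test of the interaction itself in 6384 genes, and the signed median over genes changed by osteoclasts was 0.64. Camera singled out the medians of YAP targets (-0.71), hypoxia and glycolysis (-0.55), nuclear-encoded oxidative phosphorylation (-0.79), lysosome and autophagy (-0.58), ribosomal proteins (-0.69) and replication-dependent histones (-2.31). With an estimated correlation it called 0 of these 6 lists (adjusted p = 0.642 for each), and GC-adjusted it no longer called YAP targets, lysosome and hypoxia (adjusted p = 0.706, 0.195 and 0.0535). Of the genes named above for the interaction, edgeR singled out Alpl (-0.68), Col1a1 (-0.76), Ehmt2 (-1.22), Grn (-1.24), Hist2h2ac (-4.19), Hmox1 (-0.83), Ifitm5 (-2.29), Kdm4b (-1.64), Mmp13 (1.35), Mt2 (-1.86), Pfkl (-1.64), Phospho1 (-1.48), Rps16 (-3.42), Smpd3 (-0.90), Sp7 (-0.46), Spp1 (1.07), Srf (-1.39), Uqcrq (-1.95). GC-adjusted, Alpl, Col1a1, Ehmt2, Hmox1, Phospho1, Smpd3, Sp7 and Srf were no longer called. Phex (1.08) and Setd7 (0.48), named above for other comparisons, also had a called interaction (edgeR adjusted p = 0.0096 and 0.0126). GC-adjusted they were not called, at 0.03 and 0.21 (adjusted p = 0.946 and 0.159). Neither is in the counts of named genes for the interaction. Among 100 regroupings of the 12 libraries, 1 (the real one) gave as many interaction calls, with 848 the highest of the others. This argues only against groups that do not differ at all. It does not test the interaction alone, since regrouping puts differences between the groups into the spread. For the signed median, only 2 regroupings called at least 5 genes in the averaged effect; the real one gave 0.64 and the other -0.18 (1 of 2 as far from 0), too few for a share under 0.05.

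The larger osteoclast effect on nanotopography was weighed against library bias. If the trend with GC content and length were the whole cause, removing it would end the shift. The signed median fell to 0.16 and stayed above 0 with fry still calling it, as in 22 of the 22 settings run. Genes and signs came from an average that includes the nanotopography contrast, so a wider spread there from any source favours a positive median. GC-adjusted, the SD of log2 fold changes over tested genes was 0.69 with osteoclasts on nanotopography and 0.52 on control titanium. The remaining shift therefore does not weigh against other technical causes. Coculture nano replicate 1 had the highest share of mitochondrial ribosomal RNA, and without it the median was 0.54 and called by fry, which argues against that library as the whole cause. Much of the size may still be technical, since the share of genes with a smaller effect on nanotopography went from 19.3% to 35.9% with the trend removed. A surface-dependent response is a hypothesis that stays open beside RNA quality, which the labels do not give.

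Macrophage and osteoclast transcripts in the co-culture libraries may be RNA or cells carried over from the insert. Of the markers near absent from isolated cells, 10 of 10 were higher in co-culture on nanotopography than on control titanium, but the count decides nothing. The markers were chosen after their values were seen, and 0 of the 10 would reach the required 10 counts on control titanium alone, against 9 on nanotopography alone. Carry-over of cells, carry-over of free RNA and expression in the MC3T3-E1 cells cannot be told apart. The most abundant listed gene, Ctsk, is also abundant in isolated cells, so it gives no estimate of the share. Lpl, Clec5a, Itga4 and Dock2, with few or 0 counts in isolated cells, are not in the marker lists and could share that source or not. The same holds for Nos2 and Gpnmb, near absent from isolated cells on control titanium.

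The hypoxia and glycolysis list had a lower median on nanotopography in co-culture. With the GC and length trend removed the list stayed lower (camera adjusted p = 6.85e-04; median -0.39 before and -0.24 after), which argues against the trend as the whole cause, though no setting of camera with an estimated correlation called the list (adjusted p = 0.573 and 0.834). For the smaller osteoclast response of the same list, the interaction median went from -0.55 to -0.18 and camera's adjusted p from 0.0027 to 0.0535, so whether the surface or the GC trend produced it cannot be told apart.

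The splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. In each comparison 1 of the 10, the real split, gave as many calls: 2637 for osteoclasts on control titanium (highest other 0), 7890 on nanotopography (0), 1347 for the surface without osteoclasts (959) and 5602 with osteoclasts (0). Among 100 regroupings, 1 gave as many calls as the averaged osteoclast effect (6301, highest other 1693) and 3 as many as the averaged surface effect (528, highest other 3416). Both shares are under 0.05, which argues only against groups that do not differ at all. Regrouping puts differences between the groups into the spread, so chance is not excluded for either effect by itself. For the averaged surface effect the share is also weak: 2 other regroupings gave 3416 and 3033 calls, which points to a structure of the samples that was not tested, and leaving out 1 library gave 221 to 652.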

How the results depend on the processing

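The GC and length adjustment, its form with a replicate block, the run without 3 libraries and the GC-band test were chosen after the data were seen.

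RLE and upper-quartile scaling, DESeq2, limma-voom, protein-coding genes only, no mitochondrial genes, a filter of 1 CPM in 3 libraries, the replicate block and only the groups compared moved no count of called genes by over 1.5 times. Upper-quartile scaling split osteoclasts on control titanium into 1168 higher and 1475 lower (44.2% higher against 55.7%), the surface with osteoclasts into 2923 and 2771 (51.3% against 44.4%) and the interaction into 3243 and 3142 (against 2999 and 3385). The adjustment split the surface without osteoclasts into 496 and 261 (65.5% higher against 44.3%) and the averaged surface effect into 234 and 336 (41.1% against 11.4%). No clear pairing of samples by replicate number was seen: correlations ran from -0.39 to 0.30 over 18 pairs, and 4 of 12 libraries were closest to their own number. These values do not exclude that some samples with the same number belong together. With a block, counts were 2473, 7760, 1346, 5467, 6248, 6211 and 501 for osteoclasts on control titanium and on nanotopography, the surface without and with osteoclasts, the interaction and the averaged osteoclast and surface effects.

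In that order, a fold of at least 2 gave 553, 3087, 132, 1268, 3159, 898 and 26 genes, by its construction. Without a low-count filter the surface without osteoclasts gave 2104 and the averaged surface effect 975. The GC and length adjustment gave 757 for the surface without osteoclasts, 2357 with osteoclasts and 2789 for the interaction; with the block as well it gave 5081 for osteoclasts on nanotopography and 587, 2098 and 2510 for those 3. Without coculture nano replicate 1 and isolated nano replicates 1 and 3, which leaves 1 isolated library on nanotopography, assumed to vary like the others, the counts were 3217 for osteoclasts on nanotopography, 2 and 3694 for the surface without and with osteoclasts, 1884 for the interaction and 4041 for the averaged osteoclast effect; fewer libraries were tested. List calls over all contrasts numbered 67, against 6 with an estimated correlation, 127 with fry and 15 with the adjustment and an estimated correlation. Other causes were not tested.

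Leaving out 1 library gave 1432 to 2979, 6737 to 8128, 2 to 2912, 3271 to 5948, 5320 to 6952, 5520 to 6774 and 221 to 652 genes in the same order, 67 to 76 list calls and signed medians from 0.54 to 0.80. Over the named genes and the libraries left out, 1557 calls were as before, 66 were lost, 9 gained and 0 reversed.

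With the adjustment, 111 of the named values kept their call or lack of one, 9 lost the call and 5 gained one. The 111 include values that changed sign but were not called either way. Examples are Sp7 and Col1a1 for the surface without osteoclasts and Bglap with osteoclasts on control titanium. Of the values counted, the following turned direction and were called with or without the adjustment. Each is given with the adjusted log2 value (and with the block where it differed). For osteoclasts on nanotopography they were Alpl (0.23), Bglap (0.41), Bglap2 (0.86 and 0.83), Ehmt2 (0.013 and 0.014), Ezh2 (-0.073 and -0.075), Kdm6b (0.64) and Phex (-0.23 and -0.22). For the surface with osteoclasts it was Sp7 (0.0999 and 0.0981). For the interaction they were Alpl (0.13), Col1a1 (0.076 and 0.073) and Sp7 (0.17 and 0.16). For the surface with osteoclasts the immediate early list (direction 1) and the mitochondrially encoded list (direction -1) also turned under the adjustment, with and without an estimated correlation. The signed median was 0.64 with RLE, 0.63 with upper-quartile scaling, 0.66 with the block, 0.16 with the adjustment, 0.39 without the 3 libraries, 1.07 at a fold of at least 2, 0.46 for the osteoblast list and 0.19 for genes of 47 to 51% GC. At this depth, interactions of 1.5-fold were recovered in 4.48% of simulated genes.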

Other observations

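No tests beyond those above were run for this part, and the values have no explanation attached.

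Galnt2 went from 148 counts in isolated cells on nanotopography to 0 in co-culture there. Mt-Rnr1 and mt-Rnr2 took more counts in coculture nano replicate 1 than in any other library.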
